A study of Mus musculus with 12 samples.

How the data were processed

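Gene expression was measured in 12 libraries of mouse muscle satellite cells, 3 animals in each of 4 groups formed by sex and Keap1 genotype, taken from the labels. Per the labels, cells were isolated from hindlimb muscle and frozen at once, total RNA was extracted with a column kit for small inputs, cDNA was made by the Smart-Seq2 method, and libraries were built with a Tn5 transposase kit. Smart-Seq2 amplifies polyadenylated RNA without molecular identifiers, so floors based on counts cover counting error only. Animal numbers in the labels are unique to each animal, so nothing pairs samples.

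Per the file headers, the deposited values are whole fragment counts per Ensembl gene, made with featureCounts 2.0.0 on exons of Ensembl GRCm38 release 99. Per the file headers, the deposited values are not estimated counts, and no value needed rounding. Per the file headers, fragments were counted without regard to strand, and neither reads mapped to several places nor reads overlapping several genes were counted. Alignment with STAR to mm10 and the use of Subread and DESeq2 are named per the submitters' processing notes, with versions other than that of featureCounts not given in the sources used here. Females and males were deposited as 2 separate tables with the same 55385 genes. Of these, 55144 were given a symbol by their Ensembl identifier from GENCODE M21, 241 had none, and 31671 had at least 1 count. The tables held 0 columns of other samples. Exonic overlap between gene models was computed from the annotation, and genes with 10% or more of their exonic bases overlapped, as well as paralogs, are given as uncertain where named.

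Total counts ran from 13042039 to 19273245 per library. A gene with 0 counts is bounded by a floor of 3 counts, which is 0.144 to 0.237 CPM on the scale of the CPM values. CPM values were computed from the deposited counts with TMM factors over all 12 libraries. Means ± SD are over 3 animals. Intervals are 95%.

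Main tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust, TMM, filterByExpr with a minimum count of 10) with Benjamini-Hochberg adjustment and a threshold of 0.05 without a fold threshold. KO-labelled and Het libraries were compared within each sex from 6 libraries. The average over the sexes, the difference of the female and the male changes, and the comparisons of the sexes came from 1 fit of all 12 libraries with 4 group means. The test within a sex stays within 1 count table. Keap1 was also tested by exact permutation of CPM. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and adjusted over all lists of a comparison. Lists with fewer than 3 tested members were left out, which left out the list of X- and Y-linked genes in females. Camera was repeated with an estimated correlation, and fry of limma was run as an alternative. Fry's directional test asks whether a list moves on balance in 1 direction and its mixed test whether members change in either direction, and neither compares the list with other genes. Counts of members are given beside most list tests, median log2 fold changes beside many and means beside a few. Overlap of female and male calls was compared with that of independent lists, and genes within 5 Mb of Keap1 were compared with all others by Fisher's exact test.

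The 32 lists were Keap1-NRF2 core components, NRF2 antioxidant and detoxification targets, pentose phosphate and NADPH enzymes, satellite cell identity and quiescence, Notch pathway, immediate early and dissociation stress genes, satellite cell activation and myogenic commitment, cell cycle, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, glycolysis, integrated stress response and ATF4 targets, endoplasmic reticulum chaperones and unfolded protein response, proteasome subunits, autophagy and lysosome, type I interferon response, NF-kB and inflammatory genes, TGF-beta, BMP and Wnt response, p53 response and apoptosis, cholesterol synthesis, X-inactivation and Y-linked sex genes, X-inactivation escape genes, sex hormone receptors and responsive genes, and markers of 8 other cell types. These were endothelium, fibro-adipogenic progenitors, blood leukocytes and macrophages, pericytes and smooth muscle, myofibres, Schwann and glial cells, tenocytes and red blood cells.

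The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Keap1 and Nfe2l2 always, and Xist, Ddx3y, Uty, Kdm5d and Eif2s3y for comparisons of the sexes. It adds the 10 higher and 10 lower genes with the smallest p among those with an adjusted p under 0.05, an absolute log2 fold change of at least 1, an average logCPM of at least 1 and no overlap of the groups. For the average it asks for the same sign in every animal in place of no overlap, and for the difference of the sexes it has no such condition. It further names up to 4 members per list past the threshold. Where the NRF2, quiescence, activation or cell cycle list has none, it takes the 2 members with the smallest p as values, and where fewer than 3 genes pass in a comparison it takes the 5 with the smallest p as values. Not every gene the rule allows is printed, and 1 is not reported here. Predicted genes are counted but not named by the rule.

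Alternatives were RLE factors, upper quartile factors, total library size, no filter, a CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma voom with quality weights, no robust estimation, an added 2-fold threshold, other-cell and mitochondrial genes left out of the library total, other choices of libraries in the fit, an additive model for the average, and leaving out each library in turn. A covariate built from the endothelial marker list (mean log2 CPM) was added after seeing the data. Each test was run on simulated counts with 200 genes changed by known folds. For 2-fold changes it recovered 55.2% in females (13734 simulated genes), 61.2% in males (13101), 64.2% for the average (14419), 25.4% for the difference of the sexes (14440), 53.7% for the sexes in Het (14449) and 65.7% in KO-labelled libraries (14435). For 1.5-fold changes it recovered 10.4%, 32.8%, 35.8%, 1.49%, 10.4% and 16.4%, and for 4-fold changes 87.9%, 93.9%, 95.5%, 66.7%, 78.8% and 92.4%. False calls made up 5.3 to 8.82% of the simulated calls. A raised list was called in each of the 6 comparisons and 0 of 100 unchanged lists were called in each. The simulated genes were drawn independently of each other, so this does not check camera calls of lists whose members move together. Dilution by other cells was first tested by comparing identity and quiescence genes between KO-labelled females and males (median -0.292), which was replaced by the difference of the changes within the sexes, since Het libraries of the sexes already differed by a median of -0.32. Levels per exon of Keap1 were not analysed here, since the counts are summed per gene.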

Results

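Total RNA was measured in muscle satellite cells, the stem cells of skeletal muscle, freshly isolated from the hindlimbs of C57BL/6J mice and snap-frozen. Each of the 12 libraries came from 1 animal. There were 3 female and 3 male animals labelled heterozygous for Keap1 (Het), and 3 female and 3 male animals labelled knockout (KO). KEAP1 is the adaptor that presents NRF2, the transcription factor encoded by Nfe2l2, for degradation, and NRF2 drives antioxidant and detoxification genes. The stated purpose was to learn how this pair of proteins acts in the maintenance and activation of satellite cells, and whether that depends on sex. The word given for the control genotype in the labels was read as heterozygous. Total counts per library ran from 13042039 to 19273245. Between 19833 and 22602 genes had at least 1 count per library, and mitochondrial transcripts took 2.2 to 2.98% of the counts. No pair of libraries of a group differed by as little as counting noise (chi-square per degree of freedom 13.9 to 74), so each was counted as 1 replicate. The first principal component held 42.3% of the variance and separated the sexes. The female and the male libraries were counted in separate tables, so a batch of preparation or sequencing cannot be told apart from sex in any direct comparison of the sexes.

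Keap1, the targeted gene (ENSMUSG00000003308, GRCm38 chromosome 9, 21229730 to 21239361), did not pass as changed between the genotypes in either sex. It stood at 9.5, 7.11 and 7.94 CPM (library-size-normalised count) in the female Het and at 11.8, 12.9 and 11 CPM in the female KO-labelled libraries, or 8.18 ± 1.21 against 11.9 ± 0.923 (mean ± SD, n = 3 each, as for all CPM values here). In males it stood at 10.1, 5.35 and 8.01 CPM in the Het and at 6.38, 7.86 and 7.65 CPM in the KO-labelled libraries, or 7.8 ± 2.36 against 7.3 ± 0.797. The log2 fold change was 0.54 ± 0.196 (SE) in females, with a 95% interval of 0.113 to 0.964 and an edgeR adjusted p of 0.186. In males the interval ran from -0.631 to 0.457, with an edgeR adjusted p of 0.936. The exact two-sided permutation p was 0.1 in females, the smallest that 3 against 3 animals allow, and 0.8 in males. It was 0.17 over both sexes with labels permuted within sex (exact, 400 arrangements). These counts are summed over all exons of the gene and cannot separate deleted from retained exons, so they do not check the genotype labels, and the libraries are called KO-labelled throughout. Of the exonic bases of Keap1, 10.9% overlap the gene model Gm16754. Nfe2l2 (chromosome 2, 75675513 to 75704641) stood at 412 ± 43.9 CPM in female Het and 462 ± 53.8 CPM in female KO-labelled libraries (edgeR adjusted p = 0.607). In the male groups it stood at 422 ± 29.7 and 470 ± 9.03 CPM (edgeR adjusted p = 0.672).

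In KO-labelled females, genes of detoxification and NADPH-producing enzymes rose. Nqo1, a quinone reductase (chromosome 8, 107388225 to 107403206), rose 20.8-fold from 4.4 ± 1.14 to 91.8 ± 15.4 CPM (edgeR adjusted p = 2.58e-07). Aldh3a1, an aldehyde dehydrogenase (chromosome 11, 61207537 to 61218421), rose 21.6-fold from 11.4 ± 2.23 to 248 ± 58.8 CPM (edgeR adjusted p = 2.58e-07). Catalase (Cat) rose 5.82-fold, the biliverdin reductase gene Blvrb 7.85-fold, the heme transporter gene Slc48a1 9.21-fold, and the lipoprotein-associated phospholipase gene Pla2g7 12.8-fold. Adh7, an alcohol dehydrogenase, rose from 0.365 ± 0.193 to 18.6 ± 3.37 CPM. Abcc4, an efflux transporter, rose 13.3-fold, Gsta4, a glutathione transferase, 11.8-fold, and Ddit4l, an inhibitor of mTOR signalling, 3.77-fold. Thbs2, the matrix glycoprotein thrombospondin, fell 5.5-fold from 239 ± 17.9 to 43.5 ± 6.14 CPM. Pthlh, parathyroid hormone-related protein, fell 8.88-fold, Oxtr, the oxytocin receptor, 4.51-fold, Rgs4, a regulator of G protein signalling, 3.32-fold, and Neu2, a cytosolic sialidase, 3.19-fold. Chrdl2, a BMP-binding protein, fell 3.73-fold from 290 ± 73 to 77.7 ± 18.6 CPM. Timp3, a metalloproteinase inhibitor, fell 2.69-fold, Spock3, a matrix proteoglycan, 4.89-fold, Ntf3, a neurotrophin, 2.8-fold, and Tmem45a 2.47-fold.

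**Figure D1:**
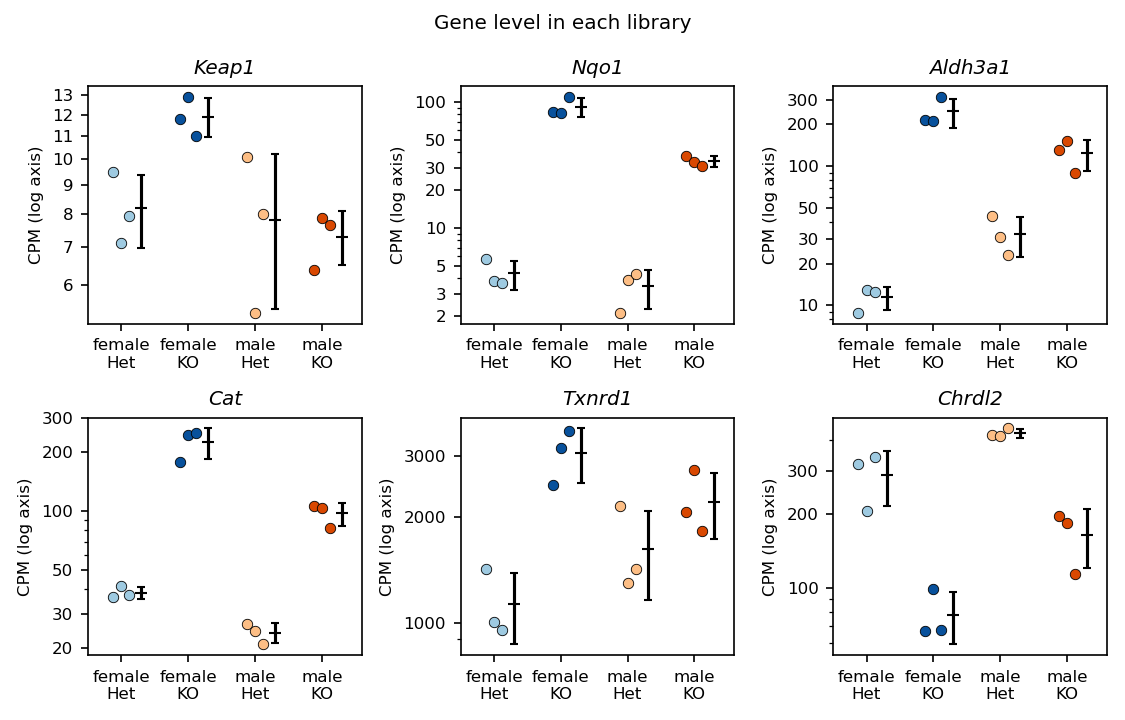
Levels of Keap1, Nqo1, Aldh3a1, Cat, Txnrd1 and Chrdl2 in CPM on a log axis, with 1 point per library in each of the 4 groups and bars for the mean ± SD (n = 3). The levels of Keap1 overlap between the genotypes in males, while Nqo1, Aldh3a1 and Cat lie higher and Chrdl2 lower in the KO-labelled libraries of both sexes.

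Among the fixed gene lists, NRF2 antioxidant and detoxification targets rose in KO-labelled females. Of 31 tested members 23 were higher and 1 was lower over all genes tested (28 and 1 adjusted over the list alone). The list had a median log2 fold change of 1.33 and a camera adjusted p of 2.24e-90 (adjusted p = 0.0197 with an estimated correlation). The lower member was Ugdh, UDP-glucose dehydrogenase (191 ± 18.4 to 120 ± 14.9 CPM), which is outside the naming rule and was chosen after its values were seen. Reads that map to several places were not counted, so the levels of glutathione transferase paralogs such as Gsta4 are uncertain. Of 9 pentose phosphate and NADPH enzymes 6 rose and 0 fell (edgeR, and the same counts adjusted over the list alone). Among them were Me1, malic enzyme (4.46-fold, 13.1 ± 1.75 to 58.8 ± 8.13 CPM), Tkt, transketolase (2.55-fold), Pgd, phosphogluconate dehydrogenase (3.27-fold), and Taldo1, transaldolase (1.95-fold). That list had a median of 0.96 and a camera adjusted p of 1.17e-14 (adjusted p = 0.0197 with an estimated correlation). In glycolysis 3 of 15 members rose (4 adjusted over the list alone), the isomerase gene Gpi1 (2.27-fold), the glucose transporter gene Slc2a1 (1.78-fold) and the enolase gene Eno1 (1.53-fold). Its median was 0.26 with a camera adjusted p of 0.00187 (adjusted p = 0.522 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.41 and a camera adjusted p of 3.64e-10 (adjusted p = 0.892 with an estimated correlation). Of 55 members 1 passed by itself, Rps20 (169 ± 37.4 to 320 ± 80.9 CPM), and 0 adjusted over the list alone.

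Immediate early and dissociation stress genes were lower in KO-labelled females. Of 30 members 6 fell and 0 rose (8 fell adjusted over the list alone), including Btg2, an antiproliferative factor (530 ± 58.3 to 266 ± 11.9 CPM), Ier2 (1.74-fold), the MAP kinase phosphatase gene Dusp1 (1.82-fold) and the cochaperone gene Dnajb1 (1.69-fold). The median was -0.31 with a camera adjusted p of 1.83e-05 (adjusted p = 0.523 with an estimated correlation). Of 16 endoplasmic reticulum chaperone and unfolded protein response genes 1 fell, Creld2, a disulfide isomerase (1.72-fold), and 12 fell adjusted over the list alone. The median was -0.44 with a camera adjusted p of 2.51e-08 (adjusted p = 0.522 with an estimated correlation). The share of counts in the mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2, looked at after the results were seen, also moved with genotype, from 0.302 to 0.507% in female Het to 0.733 to 1.03% in female KO-labelled libraries. It ran the other way in males, 0.409 to 0.601% in Het and 0.226 to 0.407% in KO-labelled libraries, and whether it bears on these lists was not tested. Of 20 satellite cell identity and quiescence genes 3 fell and 0 rose (6 lower and 3 higher adjusted over the list alone). These were Chrdl2, Cd34, a surface sialomucin (136 ± 27.2 to 70.1 ± 6.54 CPM), and Spry1, an inhibitor of growth factor signalling (215 ± 24.2 to 102 ± 27.6 CPM). The list did not pass (median -0.12, camera adjusted p = 0.0502). In the activation and commitment list Cdkn1a, a cyclin-dependent kinase inhibitor, fell 1.57-fold and 17 of 18 members did not pass (2 lower adjusted over the list alone). That list did not pass either (median 0.05, mean -0.04, camera adjusted p = 0.81). Of 30 cell cycle genes 0 passed with edgeR, also adjusted over the list alone, and the list's median was 0.23 (camera adjusted p = 0.309). The members with the smallest p were E2f1 (edgeR adjusted p = 0.239) and Cdt1 (edgeR adjusted p = 0.276).

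Markers of other cells moved beside these groups in females. Leukocyte and macrophage markers were lower in KO-labelled females, with a median of -0.85 and a camera adjusted p of 1.79e-05 (adjusted p = 0.0776 with an estimated correlation). Of 15 members 2 fell (3 adjusted over the list alone), the invariant chain gene Cd74 (61.5 ± 13.2 to 22.7 ± 7.02 CPM) and the lysozyme gene Lyz2 (23.3 ± 6.43 to 10.1 ± 3.48 CPM). The summed CPM of that list was 90.87 to 125.2 in female Het and 38.32 to 56.55 in female KO-labelled libraries. Fibro-adipogenic progenitor markers had a median of -0.38 and a camera adjusted p of 0.0335 (adjusted p = 0.522 with an estimated correlation), with 0 of 15 members past the threshold in edgeR and 2 lower adjusted over the list alone. That call was lost without Het165, Het181, KO166 or KO178. Endothelial markers did not pass (median 0.46, camera adjusted p = 0.0722). The Schwann cell marker Ptprz1 fell 1.82-fold and the pro-apoptotic gene Pmaip1 2.58-fold, while the NRF2 competitor gene Bach1 (1.62-fold), the growth factor gene Tgfb1 (2.3-fold) and the lysosomal protease gene Ctsd (1.57-fold) rose, each in a list that did not pass. The exons of Ctsd (34.4% of bases), Spry1 (24.4%), Timp3 (21.3%) and Pla2g7 (11%) overlap other gene models, and unstranded counts leave these genes uncertain.

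Of 14036 genes tested in females, 319 passed an adjusted p of 0.05 (56.7% higher, 138 genes lower in KO-labelled animals), and 207 of them changed at least 2-fold (132 higher, 75 lower). In all 319 the 3 KO-labelled libraries lay apart from the 3 Het libraries, which chance gives for 10% of genes and which held for 22.3% of all genes tested. DESeq2 called 328 genes higher and 379 lower. Without Het165 the count was 1479 (311 of the 319 among them), without Het164 198 and without Het181 202. Without KO166, KO178 or KO188 it was 52%, 63.9% or 45.1% of 319. Of the 43 named genes that passed in females, 24 passed in every alternative setting run for single genes (all but the 2-fold threshold). Without KO188, 15 were lost (adjusted p 0.0513 to 0.234), namely Bach1, Cdkn1a, Creld2, Ctsd, Dnajb1, Dusp1, Eno1, Ier2, Lyz2, Pmaip1, Ptprz1, Rps20, Slc2a1, Spry1 and Tgfb1. Without KO166, 12 were lost, Cd34 and 11 of those (0.0566 to 0.167), and without KO178, Het164 or Het181, 11, 8 or 8 of those (0.0515 to 0.183). Without Het165, Pmaip1 was lost (0.061). In the fit of all 12 libraries 6 were lost, among them Pthlh (0.195), Tmem45a (0.267) and Cd74 (0.16).

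In KO-labelled males, Nqo1 rose 9.63-fold from 3.46 ± 1.18 to 33.9 ± 3.1 CPM (edgeR adjusted p = 1.15e-05) and other detoxification genes rose with it. Cat rose 4.07-fold from 24.0 ± 2.81 to 97.4 ± 13.3 CPM, Blvrb 3.66-fold, Mgst1, a microsomal glutathione transferase, 3.42-fold, Slc48a1 4.39-fold and Pla2g7 13.3-fold. Ces2c, a carboxylesterase, rose from 0.358 ± 0.119 to 8.73 ± 0.496 CPM, Akr1c14, an aldo-keto reductase, 17.0-fold, Panx1, a channel protein, 4.25-fold and Adh7 16.1-fold. Nppc, C-type natriuretic peptide, fell 4.93-fold from 31.2 ± 3.91 to 6.34 ± 2.53 CPM. Chrdl2 fell 2.59-fold from 428 ± 17.8 CPM, and Thbs2 2.29-fold from 634 ± 234 to 276 ± 39.4 CPM. Ryr3, a ryanodine receptor, fell 2.24-fold, Mgarp 2.85-fold, the amino acid transporter gene Slc38a3 3.11-fold and Arhgap20 2.02-fold.

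NRF2 targets had 13 of 28 tested members higher and 0 lower in KO-labelled males (edgeR; 16 and 0 adjusted over the list alone). The median log2 fold change was 0.54 with a camera adjusted p of 1.03e-40 (adjusted p = 0.161 with an estimated correlation). Of 9 pentose phosphate and NADPH enzymes 2 rose, Me1 (8.75 ± 2.91 to 31.5 ± 2.8 CPM) and Tkt (1.56-fold), also adjusted over the list alone. Their median was 0.37 with a camera adjusted p of 0.000103 (adjusted p = 0.161 with an estimated correlation). Cholesterol synthesis genes rose, with a median of 0.45 and a camera adjusted p of 2.02e-07 (adjusted p = 0.993 with an estimated correlation). Of 20 members 3 passed, the sterol oxidase gene Msmo1 (153 ± 18.3 to 265 ± 40.9 CPM), the squalene synthase gene Fdft1 (1.86-fold, 18.8% of its exonic bases shared with Ctsb) and the isomerase gene Idi1 (1.66-fold), and 10 were higher and 1 lower adjusted over the list alone. Ribosomal protein genes (median -0.11, camera adjusted p = 0.0011) and proteasome subunits (median -0.08, camera adjusted p = 0.04) were lower as lists, each with an adjusted p of 0.993 with an estimated correlation. No member of either passed with edgeR (0 of 55 and 0 of 31, also adjusted over the list alone). The ribosomal call was lost without Het249 or KO240, and the proteasome call without Het245, Het249, KO240 or KO255, with an opposite median without KO255. The TGF-beta family gene Gdf15 (25.9 ± 0.716 to 56.3 ± 5.3 CPM) and the receptor gene Notch2 (86 ± 10.2 to 138 ± 4.77 CPM) rose and Id1, an inhibitor of differentiation, fell 1.82-fold, in lists that did not pass.

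Satellite cell lists did not pass in males. Of 20 identity and quiescence genes 1 fell, Chrdl2 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.384). Of 15 activation genes 0 passed with edgeR (0 adjusted over the list alone; camera adjusted p = 0.384). Those with the smallest p were Myog, a commitment factor, at 7.8 ± 3.11 and 17.9 ± 7.87 CPM (edgeR adjusted p = 0.206), and Ncam1 (edgeR adjusted p = 0.3). Of 28 cell cycle genes 0 passed with edgeR (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.384), with the helicase genes Mcm3 (edgeR adjusted p = 0.124) and Mcm7 (edgeR adjusted p = 0.168) at the smallest p.

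Of 13361 genes tested in males, 115 passed (94 higher, 21 lower), 61 of them at least 2-fold (53 higher, 8 lower). All 115 had libraries that lay apart, against 10% by chance and 17.2% over all genes. DESeq2 called 264 genes and limma voom 374. Without Het204, Het245, Het249 or KO240 the count was 55, 67, 44 or 41, and without KO247 or KO255 it was 229 or 294. Of the 25 named genes that passed, 14 passed in every alternative setting run for single genes (all but the 2-fold threshold). The others were Arhgap20, Fdft1, Id1, Idi1, Mgarp, Msmo1, Notch2, Ryr3, Slc38a3, Thbs2 and Tkt, and all 11 were lost without Het249 (adjusted p 0.0637 to 0.257). Without KO240, Het204 or Het245, 9, 8 or 8 of them were lost (0.0558 to 0.319). Without KO255, Id1 and Thbs2 were lost (0.0839 to 0.144), and without KO247 Thbs2 (0.0973). In the fit of all 12 libraries 7 were lost (0.0679 to 0.198).

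**Figure D2:**
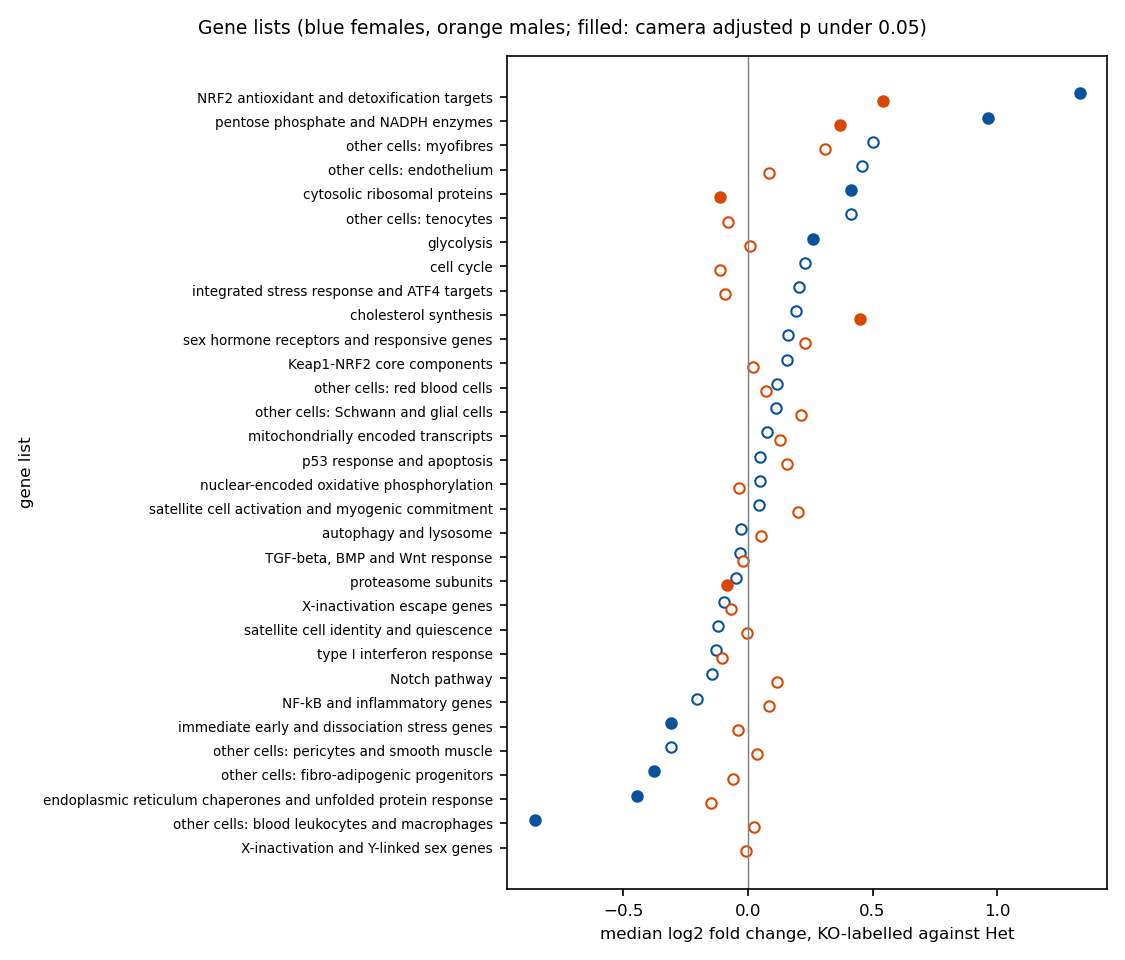
Median log2 fold change, KO-labelled over Het, of the members of each of the 32 fixed gene lists, with females in blue and males in orange and filled points where camera with a preset correlation gave an adjusted p under 0.05. The NRF2 target list and the list of pentose phosphate and NADPH enzymes lie to the right in both sexes, and the list of X- and Y-linked sex genes was not tested in females.

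The genes called in females and in males overlapped. Among 13062 genes tested in both sexes, 51 were higher in both (1.17 expected from independent lists) and 8 were lower in both (0.22 expected). Genes higher in both included Nqo1, Cat, Blvrb, Slc48a1, Pla2g7, Adh7 and Me1, and genes lower in both included Chrdl2 and Thbs2. Of 301 female calls 246 had the same sign in males, and of 114 male calls 98 had the same sign in females. The log2 fold changes of the sexes correlated across genes with r = 0.314 and rho = 0.151, where genes are not independent replicates.

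**Figure D3:**
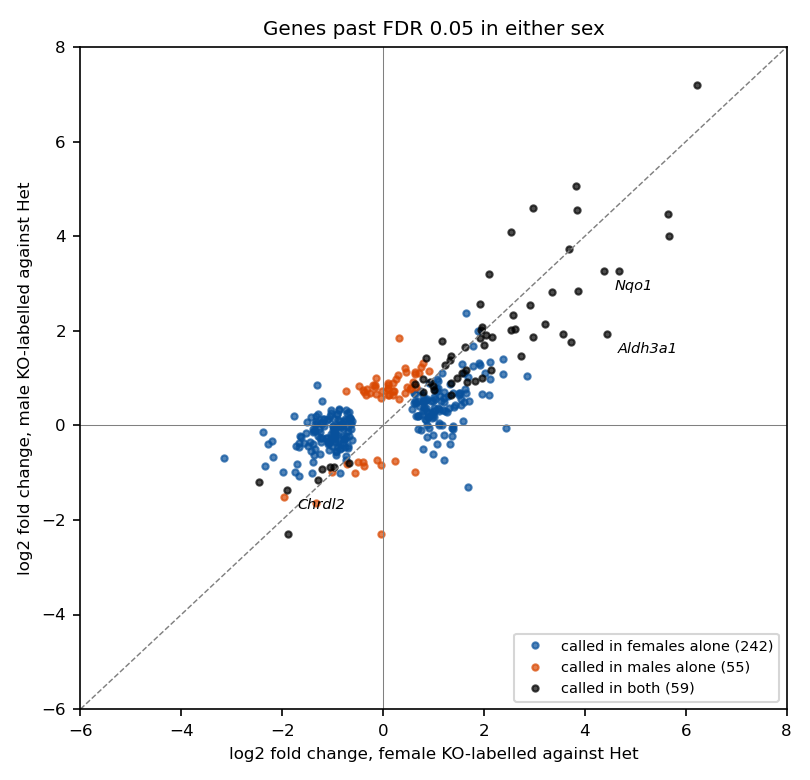
Log2 fold change, KO-labelled over Het, in males against females for genes that passed in either sex, with 242 that passed in females alone in blue, 55 in males alone in orange and 59 in both in black. The dashed line marks equal change, and 51 of the black points lie in the upper right.

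Averaged over both sexes, genes of detoxification rose. Nqo1 rose 14.2-fold, Blvrb 5.36-fold, Pla2g7 13-fold, Cat 4.87-fold, Slc48a1 6.36-fold, Adh7 28.6-fold, Abcc4 6.69-fold, Akr1c14 9.96-fold and Aldh3a1 9.1-fold. Thbs2 fell 3.55-fold, Chrdl2 3.11-fold, Nppc 4.27-fold, Spock3 2.54-fold, Slc1a3, a glutamate transporter, 2.41-fold, Ryr3 2.34-fold and Rgs4 2.12-fold. Neu2 fell 2.1-fold, Pcsk5, a proprotein convertase, 2.09-fold and Has1, a hyaluronan synthase, 2.03-fold. Of 20 identity and quiescence genes 3 fell, also adjusted over the list alone, Chrdl2, Spry1 (1.65-fold) and Cd34 (1.45-fold), and the list did not pass (camera adjusted p = 0.0664). Hgf, which encodes hepatocyte growth factor, fell 1.92-fold as the 1 of 18 activation genes to pass (1 higher and 1 lower adjusted over the list alone), and that list did not pass (camera adjusted p = 0.708). Of 30 cell cycle genes 0 passed with edgeR, with Mcm7 (edgeR adjusted p = 0.0726) and Rrm2 (edgeR adjusted p = 0.136) at the smallest p.

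Across both sexes, 24 of 31 NRF2 targets rose and 1 fell (27 and 1 adjusted over the list alone). Their median was 0.94 with a camera adjusted p of 7.95e-99 (adjusted p = 0.00113 with an estimated correlation). Of 9 pentose phosphate and NADPH enzymes 6 rose (7 adjusted over the list alone), led by Me1 (4.03-fold), Pgd (2.17-fold) and Tkt (1.99-fold), with a camera adjusted p of 5.25e-14 (adjusted p = 0.00151 with an estimated correlation). Glycolysis was higher as a list (camera adjusted p = 0.00575, but adjusted p = 0.505 with an estimated correlation), with 3 of 15 members higher (4 adjusted over the list alone), Gpi1 (1.69-fold), Slc2a1 (1.59-fold) and Eno1 (1.57-fold). Cholesterol synthesis was higher as a list (camera adjusted p = 0.000139, but adjusted p = 0.698 with an estimated correlation), with Msmo1 and Cyp51 past the threshold (8 higher and 1 lower adjusted over the list alone). Endoplasmic reticulum chaperones were lower (camera adjusted p = 1.35e-06, but adjusted p = 0.808 with an estimated correlation), with 1 of 16 past the threshold, Creld2 (9 adjusted over the list alone). Immediate early genes were lower (camera adjusted p = 0.00666, but adjusted p = 0.972 with an estimated correlation), with 3 of 30 lower, Btg2, Ier2 and Jun (5 lower and 1 higher adjusted over the list alone). Ribosomal protein genes had a median of 0.11 and a camera adjusted p of 0.00575 (adjusted p = 0.972 with an estimated correlation), with 0 of 55 past the threshold in edgeR, also adjusted over the list alone. Their medians were 0.414 in females and -0.112 in males, so that average describes neither sex. In males alone, glycolysis (camera adjusted p = 0.639), endoplasmic reticulum chaperones (0.144) and immediate early genes (0.779) did not pass. In females alone, cholesterol synthesis did not pass (camera adjusted p = 0.247). The ribosomal call was lost without female Het181 or female KO188, and the immediate early call without female Het165 or male KO247. In lists that did not pass, Mafg, which encodes a partner of NRF2, rose 1.3-fold, Tgfb2, Bmp2, Ctsd, Hexa and Gdf15 rose, and Pmaip1, the endothelial receptor gene Tek, Cxcl14 and Ptprz1 fell. In all, 504 of 14772 genes passed (317 higher, 187 lower), 138 at least 2-fold. DESeq2 called 821 genes and limma voom 852. Without female Het165 the count was 931, and without female KO188, male Het249 or male KO240 it was 318, 332 or 325. Of the 46 named genes that passed, 30 passed in every alternative setting run for single genes (all but the 2-fold threshold), and leaving out 1 library lost up to 10 (male Het249, adjusted p 0.0563 to 0.122), among them Bmp2, Cxcl14, Cyp51, Hgf, Jun, Mafg, Tek and Tgfb2. The additive model of sex and genotype lost 11 (adjusted p 0.0551 to 0.171), Bmp2, Btg2, Cd34, Creld2, Ier2, Jun, Msmo1, Pgd, Pmaip1, Spock3 and Tgfb2.

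Whether the change with genotype depended on sex was tested as the difference of the female and the male changes. Aldh3a1 alone passed, with a change 5.69-fold larger in females (log2 difference 2.51 ± 0.344 SE, edgeR adjusted p = 0.0319). It went from 11.4 ± 2.23 to 248 ± 58.8 CPM in females and from 32.6 ± 10.4 to 124 ± 30.9 CPM in males. That call was lost without female Het181 (adjusted p 0.0957), female KO188 (0.0643), male Het245 (0.0905) or male KO240 (0.114). Below the threshold, the log2 difference was 1.99 for Abcc4 (edgeR adjusted p = 0.0732), 1.30 for Ptov1 (edgeR adjusted p = 0.076) and 1.10 for Blvrb (edgeR adjusted p = 0.0775). It was -1.20 for Zfp948, -1.89 for Spock3 and 3.0 for Mir6236, with the same adjusted p as Blvrb. Keap1 had a difference of 0.63 (edgeR adjusted p = 0.428). Members of the satellite cell lists did not pass, such as Cd34 (-0.85, edgeR adjusted p = 0.169), Foxo3 (-0.85, 0.218), Cdkn1a (-0.79, 0.22), Myf6 (-1.61, 0.252), Mcm3 (0.94, 0.32) and E2f1 (1.36, 0.379). Of 14772 genes, 1829 had an unadjusted p under 0.05. DESeq2 called 243 genes (75 with a higher and 168 with a lower change in females), limma voom 66 and edgeR without a filter 358. Leaving out female Het165 gave 206 genes, and leaving out female Het164, KO166 or KO178 or male Het249, KO247 or KO255 gave 6, 4, 3, 2, 4 or 10.

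As a list, the NRF2 targets changed more in females than in males. The median of the 31 differences was 0.76 on the log2 scale (camera adjusted p = 4.04e-12, but adjusted p = 0.36 with an estimated correlation). With edgeR 0 members passed over all genes, and 17 were higher and 2 lower adjusted over the list alone. The mean log2(CPM + 1) of the list rose by 1.43 in females and 0.72 in males, a difference of 0.713. Its two-sided permutation p was 0.04 (exact, sex permuted within genotype, 400 arrangements). That permutation assumes no difference between the sexes in either genotype, so its p does not test the difference of the changes alone. The library means lay apart between KO-labelled females (6.83 to 7.048) and males (6.037 to 6.427). They overlapped between Het females (5.355 to 5.666) and males (5.441 to 5.721). Ribosomal protein genes (median 0.53, camera adjusted p = 4.58e-19, 25 of 55 adjusted over the list alone), pentose phosphate and NADPH enzymes (0.61, 0.00424, 4 of 9) and glycolysis (0.22, 0.0377, 2 of 15) also had a more positive change in females. A more negative one was seen in immediate early genes (-0.27, camera adjusted p = 0.00132, 5 of 30 adjusted over the list alone), endoplasmic reticulum chaperones (-0.30, 0.00247, 2 of 16), activation genes (-0.33, 0.0377, 0 of 18) and cholesterol synthesis (-0.31, 0.0377, 0 of 20). Among markers of other cells it was seen in those of leukocytes (-1.08, mean -0.499, camera adjusted p = 0.023, 2 of 15 adjusted over the list alone) and fibro-adipogenic progenitors (-0.35, 0.0364, 1 of 15). With an estimated correlation none of these 10 lists passed (adjusted p 0.36 to 0.654). With 1 library left out, 6 (female Het165) to 16 (male KO247) lists passed, and these were not always the same lists. Of 480 values of lists under alternatives in this comparison, 46 lost the call and 25 gained one.

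Between the sexes, Het libraries differed in sex-linked genes and in markers of other cells. Xist, the RNA that silences an X chromosome, stood at 330 ± 78.3 CPM in females and 0.184 ± 0.142 CPM in males. The Y-linked genes had 0 counts in the female Het libraries, so that against a floor of 3 counts per library Ddx3y was at least 5080-fold, Eif2s3y at least 560-fold, Uty at least 401-fold and Kdm5d at least 77.7-fold higher in males. The list of these 5 genes passed (camera adjusted p = 7.43e-75, and adjusted p = 2.01e-05 with an estimated correlation), with 1 higher and 4 lower in females, also adjusted over the list alone. All 14 endothelial markers were lower in female Het libraries, also adjusted over the list alone (median -2.14, camera adjusted p = 5.16e-18, but adjusted p = 0.146 with an estimated correlation). Among them were the water channel gene Aqp1 (24.3 ± 3.06 against 140 ± 15.8 CPM), Pecam1 (8.22 against 27.3 CPM) and Fabp4 (8.25 against 36.2 CPM). Their summed CPM was 98.6 to 106.3 in female and 383.9 to 422.5 in male Het libraries. Greb1, an oestrogen-responsive gene, was 49.4-fold higher in females (22.1 ± 5.01 against 0.448 ± 0.242 CPM), and the oestrogen receptor gene Esr1 was lower (69.5 against 106 CPM). Esm1, Sema3a, Akr1c14, P2ry14 and Ppic were also among the higher genes with the smallest p, and Edn1 (7.14-fold), Dab2, Cxcl5, Slco4a1 and Sorcs2 among the lower. For Keap1 the log2 difference was 0.08 (edgeR adjusted p = 0.875).

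Female Het libraries had higher levels of activation and cell cycle genes than male Het libraries. Of 18 activation genes 5 were higher (6 higher and 1 lower adjusted over the list alone), including Myog (41.0 ± 10.4 against 7.8 ± 3.11 CPM) and the embryonic myosin gene Myh3 (15.9-fold). The list had a camera adjusted p of 0.000222 (adjusted p = 0.144 with an estimated correlation). Myofibre markers were higher too, with 1 of 13 members past the threshold, Myh1 (7.78 against 0.855 CPM), and 8 adjusted over the list alone (camera adjusted p = 4.32e-05, but adjusted p = 0.44 with an estimated correlation). Of 30 cell cycle genes 5 were higher, such as the cyclin gene Ccna2 (5.23 against 1.23 CPM) and Cdc20 (11.9 against 5.27 CPM), and the reductase subunit gene Rrm2 was lower (24.2 against 68.8 CPM). Adjusted over the list alone, 14 were higher and 1 lower (camera adjusted p = 0.000174, but adjusted p = 0.44 with an estimated correlation). The p53 list had 7 of 20 members higher, such as Zmat3 (33.8 against 8.92 CPM) and Eda2r (196 against 97.6 CPM), and 1 lower (10 and 1 adjusted over the list alone). Its camera adjusted p was 8.07e-05 (adjusted p = 0.198 with an estimated correlation). Of 6 X-inactivation escape genes 3 were higher, also adjusted over the list alone, such as the demethylase gene Kdm6a (97.3 against 47.0 CPM). The list had a camera adjusted p of 0.000826 (adjusted p = 0.0626 with an estimated correlation).

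Inflammatory genes were lower in female than in male Het libraries. Of 19 NF-kB and inflammatory genes 8 were lower (12 adjusted over the list alone), such as Cxcl1 (1000 against 2710 CPM) and Il6 (10.6 against 27.0 CPM), with a camera adjusted p of 6.54e-06 (adjusted p = 0.241 with an estimated correlation). Of 20 interferon genes 6 were lower (8 adjusted over the list alone), such as Isg15, Ifit2 and Irf7, with a camera adjusted p of 5.73e-05 (adjusted p = 0.358 with an estimated correlation). Ribosomal proteins (7 of 55 lower, 24 adjusted over the list alone, camera adjusted p = 5.33e-10) and cholesterol synthesis (3 of 20, 6 alone, 0.00151) were lower as lists, as were immediate early genes (4 of 30 lower and 1 higher, 7 and 2 alone, 0.00607) and mitochondrial transcripts (2 of 11, 3 alone, 0.0302). With an estimated correlation their adjusted p was 0.448, 0.44, 0.583 and 0.44. Markers of tenocytes (5 of 8, 5 adjusted over the list alone, camera adjusted p = 0.000115), red blood cells (1 of 5, 4 alone, 0.00151) and Schwann cells (3 of 9, 3 alone, 0.00289) were lower, with an adjusted p of 0.0403, 0.358 and 0.218 with an estimated correlation. Leukocyte markers (2 of 15 higher and 1 lower, also adjusted over the list alone, camera adjusted p = 0.019) and endoplasmic reticulum chaperones (2 of 16 higher, 2 alone, 0.0123) were higher, with an adjusted p of 0.44 and 0.583 with an estimated correlation. Among the calls lost were that of leukocytes without male Het249 and with total library size, and that of mitochondrial transcripts without male Het249. Not every loss is named, and 27 values of lists under alternatives lost the call in this comparison. The NRF2 target list did not pass (5 of 31 higher, such as Cbr3 at 21.1 against 8.97 CPM and Cat at 38.5 against 24.0 CPM, and 3 lower; camera adjusted p = 0.935). Identity and quiescence genes did not pass either (1 higher, the cell cycle inhibitor gene Cdkn1c, which has 30.7% of its exonic bases overlapped, and 1 lower, Sdc4 at 7230 against 10600 CPM; camera adjusted p = 0.156).

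Between Het libraries 1501 genes passed (697 higher, 804 lower in females), 683 of them at least 2-fold. Scaling by total library size, which moved the median of all genes by 0.108 on the log2 scale, gave 1058 higher and 561 lower, so these directions are relative to the TMM scale. With the endothelial marker score as a covariate, chosen after seeing the data, 35 passed, and 88 of the 102 named genes that had passed did not, Myog, Cat, Ccna2, Cxcl1 and Fabp4 among them. The median size of the log2 difference of the 1501 genes then went from 0.923 to 0.725, its median SE from 0.208 to 0.393, and 1453 kept their sign. Without male Het204 or male Het249 the count was 668 or 763, and leaving out 1 library lost 12 (female Het165) to 33 (male Het204) of the named genes, with Sdc4 lost in 4 of the 6 cases.

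**Figure D4:**
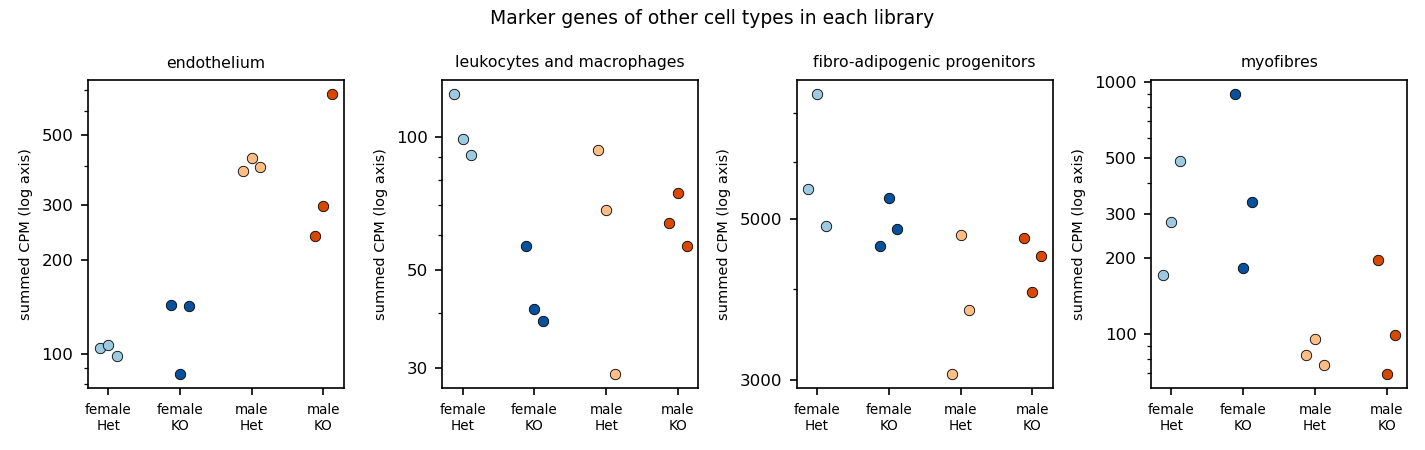
Summed CPM of the fixed marker lists of endothelium, leukocytes and macrophages, fibro-adipogenic progenitors and myofibres on a log axis, with 1 point per library in the 4 groups. Endothelial markers sum to 383.9 to 422.5 in the male Het and 98.6 to 106.3 in the female Het libraries, and leukocyte markers lie lower in the female KO-labelled than in the female Het libraries.

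Between KO-labelled animals, females had higher detoxification transcripts and lower quiescence and inflammatory transcripts than males. The quiescence and inflammatory lists leaned the same way between Het libraries (medians -0.32 and -0.626, against -0.292 and -0.926 here). For neither list did the difference of the female and the male changes pass (camera adjusted p = 0.298 and 0.0801). Of 31 NRF2 targets 16 were higher in females (19 adjusted over the list alone), including Cbr3, a carbonyl reductase (67.1 ± 2.4 against 16.8 ± 1.85 CPM), Cat (225 against 97.4 CPM), Abcc4 (2.98-fold) and Trim16 (43.9 against 17.6 CPM). Gstm2 was lower (1 lower adjusted over the list alone) and was chosen after its values were seen. The median was 0.69 with a camera adjusted p of 2.62e-09 (adjusted p = 0.205 with an estimated correlation). Of 9 pentose phosphate and NADPH enzymes 4 were higher (6 adjusted over the list alone), including Pgd (417 against 141 CPM) and Taldo1 (106 against 50.2 CPM), with a camera adjusted p of 0.00334 (adjusted p = 0.15 with an estimated correlation). Of 20 identity and quiescence genes 8 were lower and 2 higher (9 and 4 adjusted over the list alone). The lower ones included the proteoglycan gene Sdc4 (4860 ± 903 against 11700 ± 717 CPM), Cd34 (70.1 against 162 CPM), Spry1 (102 against 221 CPM) and the adhesion gene Vcam1 (1440 against 2690 CPM). The list had a camera adjusted p of 0.0307 (adjusted p = 0.382 with an estimated correlation), a call lost without female KO166, female KO188 or male KO255. Of 19 NF-kB and inflammatory genes 12 were lower (15 adjusted over the list alone), such as Cxcl1 (876 against 2870 CPM), with a camera adjusted p of 5.78e-08 (adjusted p = 0.197 with an estimated correlation). Of 30 immediate early genes 14 were lower (17 lower and 1 higher adjusted over the list alone), such as Dnajb1 (303 against 986 CPM) and Btg2 (266 against 623 CPM), with a camera adjusted p of 3.08e-07 (adjusted p = 0.36 with an estimated correlation). Keap1 was higher in females (log2 0.71 ± 0.223, edgeR adjusted p = 0.0329), a call lost without each of the 6 libraries in turn (0.0516 to 0.115) and with the endothelial covariate (0.287).

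Cell cycle genes were higher in KO-labelled females than males in 16 of 30 and lower in 1 (20 and 1 adjusted over the list alone). Ccna2 stood at 6.78 against 0.814 CPM, the kinesin gene Kif11 at 12.9 against 1.99 CPM and Rrm2, the lower member, at 29.1 against 127 CPM. The list had a camera adjusted p of 3.19e-06 (adjusted p = 0.382 with an estimated correlation). Cholesterol synthesis genes were lower in 10 of 20 (13 adjusted over the list alone), such as Msmo1 (104 against 265 CPM), with a camera adjusted p of 4.99e-06 (adjusted p = 0.243 with an estimated correlation). Endothelial markers were lower in 14 of 14, also adjusted over the list alone (camera adjusted p = 4.41e-08, but adjusted p = 0.36 with an estimated correlation). Their summed CPM was 85.95 to 143.5 in female KO-labelled libraries and 237.9, 297 and 678.4 (KO255) in male ones. Myofibre markers were higher in 7 of 13 (10 adjusted over the list alone; camera adjusted p = 3.84e-05, but adjusted p = 0.39 with an estimated correlation), with a summed CPM of up to 898.4 in female KO166. Interferon genes (7 of 20 lower, 9 adjusted over the list alone, camera adjusted p = 0.000664), mitochondrial transcripts (5 of 11 lower, 6 alone, 0.0135) and X-inactivation escape genes (5 of 6 higher, 5 alone, 0.00496) also passed, with an adjusted p of 0.384, 0.382 and 0.15 with an estimated correlation. The mitochondrial call was lost without female KO166 or male KO240. Markers of Schwann cells (5 of 9 lower, 5 adjusted over the list alone, camera adjusted p = 0.00343) and tenocytes (2 of 8 lower, 2 alone, 0.0195) passed as well, with an adjusted p of 0.238 and 0.197 with an estimated correlation.

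Among the genes with the smallest p between KO-labelled animals, Neu2 (62 against 421 CPM), Spock3 (3.62 against 43.7 CPM), Thbs2 (43.5 against 276 CPM) and Rgs4 (28.5 against 139 CPM) were lower in females. Foxp1, a transcription factor (160 against 51.2 CPM), Vim, vimentin (1380 against 517 CPM), and Plin2, a lipid droplet protein (103 against 33.7 CPM), were higher. Xist stood at 380 ± 45.4 against 0.118 CPM. With 0 counts in KO-labelled females and a floor of 3 counts per library, Ddx3y was at least 4710-fold, Eif2s3y at least 530-fold, Uty at least 359-fold and Kdm5d at least 78.3-fold higher in males. In this comparison 3016 genes passed (1376 higher, 1640 lower in females), 1284 of them at least 2-fold, and without female KO166 the count was 2001. Scaling by total library size moved the median of all genes by 0.167 and gave 2370 higher and 1104 lower. With the endothelial covariate 753 passed, and 71 of the 127 named genes that had passed did not, Pgd, Taldo1, Aqp1, Ccna2, Cdc20 and Kif11 among them. Of the 3016 genes 2989 kept their sign (median size 0.886 to 0.857, median SE 0.203 to 0.321).

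Genes near Keap1 were compared with other genes because sequence from another strain can travel with a targeted locus. Within 5 Mb of Keap1, 1 of 73 tested genes passed in females, Bmper (log2 -0.85, edgeR adjusted p = 0.0493), against 318 of 13962 elsewhere (Fisher's exact two-sided p = 1). In males 1 of 67 passed, Tmem205 (log2 1.16, edgeR adjusted p = 0.0306), against 114 of 13293 elsewhere (Fisher's exact two-sided p = 0.44).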

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

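The tests of exchanged libraries, of a hidden fall of Keap1, of a kept Keap1 transcript, of dilution by other cells and of the separate count tables were chosen only after the results were seen, as was the endothelial covariate. A difference between the female and the male change with genotype brought up the 11 results in this paragraph, each by the test of that difference itself. Aldh3a1 had a log2 difference of 2.51. List medians on the log2 scale were 0.763 for NRF2 targets, 0.615 for pentose phosphate and NADPH enzymes, 0.534 for cytosolic ribosomal proteins and 0.224 for glycolysis, where positive values mean a more positive change in females. They were -0.265 for immediate early genes, -0.332 for activation genes, -0.305 for endoplasmic reticulum chaperones, -0.312 for cholesterol synthesis, -0.347 for fibro-adipogenic progenitor markers and -1.08 for leukocyte markers. Of the 10 lists, 0 passed with an estimated correlation or with fry's directional test, and 4 passed fry's mixed test (NRF2 targets, pentose phosphate and NADPH enzymes, glycolysis and immediate early genes). Of 100 splits of the 12 libraries within sex, 13 gave at least 1 gene for this difference, the real split included. Of the 12 others, 10 are among the 24 splits that keep the real grouping of 1 sex and so carry the genotype effect of that sex into the difference. Of the 75 splits that do not keep it, 2 gave a gene, with 1 at the highest. The count of 13 therefore does not decide whether chance gave the 1 gene. The highest other split gave 504 genes. That split exchanges the genotype labels of the males and thereby gives the average change of both sexes, so it points to the genotype structure of the samples. The cause was not tested for any of these but the NRF2 targets, which are weighed further on.

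Keap1 counts summed over the gene did not pass as lower in KO-labelled libraries of either sex. Libraries exchanged between the genotypes are argued against, since the mean NRF2 target level of all 6 KO-labelled libraries lay above that of every Het library of their sex. In females a fall of the summed counts hidden by cells without the deletion has only weak evidence against it. The lower 95% limit of the log2 fold change was 0.113, above 0. That interval is not adjusted over genes, and the edgeR adjusted p was 0.186. Summed counts also cannot show a loss of the deleted exons alone, so the explanation stays open. In males the same explanation stays open, with a lower limit of -0.631. A transcript kept with the deleted exons missing may account for the pattern and stays open, since the average log2 fold change was 0.226 and counts per exon were not analysed here.

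NRF2 targets rose less in KO-labelled males than in KO-labelled females. After thinning all libraries to 13042039 counts the female median exceeded the male median by 0.722, against 0.659 before (28 genes), so equal totals did not shrink the difference. Random thinning leaves the expected fold changes as they are. The outcome was therefore nearly fixed in advance and carries little weight against lower depth of the male libraries. Dilution of the male KO-labelled samples by RNA of other cells was not decided by its bound. The female minus male change of identity and quiescence genes had a median of -0.131 with an interval of -0.566 to 0.389. The upper end of that interval passes the bound of 50% of the NRF2 target value (0.763). Dilution as the whole cause asks for about 0.763 there, outside the interval, through a fall in males. Within males these genes had a median of -0.00305 (interval -0.21 to 0.148). Both intervals come from resampling genes and leave out the spread between animals. By library, their mean log2(CPM + 1) was 7.738 to 7.946 in male Het and 7.599 to 7.948 in male KO-labelled samples. These values argue against dilution as the whole cause, while dilution as a part of it stays open. A fixed share of cells without the deletion in male samples may account for the smaller rise and stays open, with 66.7% of raised targets inside 2 standard errors of 1 common ratio of the male to the female rise, between the bounds of 60% and 80% set in advance. Gstm2 (5.12 ± 2.31), Mgst1 (1.31 ± 0.223), Aox1 and Blvrb lay above that ratio, and Trim16, Cbr3 (0.17 ± 0.0286), Gsta2 and Gsta3 below it. In CPM, Gstm2, Ephx1 (1.76 ± 0.795) and Mgst1 rose more in males, each with a ratio within 2 standard errors of 1. A biological difference between the sexes was not tested and stays open.

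The sexes differed in many genes besides NRF2 targets. RNA of endothelial cells as the whole cause was weighed by slopes on the endothelial marker score within groups. The 790 genes lower in females, the 14 endothelial markers left out, had a median slope of 0.126 (interval 0.102 to 0.148). The 697 genes higher in females had a slope of -0.0714 (interval -0.0915 to -0.0442), so at the median both sets followed the score weakly. The markers themselves had 1.15 (interval 1.03 to 1.27), which lies near 1 by construction, since the score is their mean. Genes that owe only a part of their counts to endothelial cells can also have slopes under 1. The slopes therefore do not settle whether endothelial RNA was the whole cause, and it stays open. A batch of the separately counted female and male samples could account for the pattern and cannot be told apart from sex, since 0 count tables hold both sexes. Biological sex was not tested apart from it and stays open as well.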

How the results depend on the processing

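The covariate of endothelial markers was chosen only after the results were seen. Of 6514 values of named genes under alternatives, 5823 kept the side of the threshold, 637 lost the call, 51 gained one and 3 changed sign with a call in at least 1 setting. Of 2103 values of lists, 1877 kept the side, 135 lost the call, 89 gained one and 2 changed sign in that way. Those that kept the side include 14 values of genes and 139 of lists that changed sign where neither setting passed. Where not stated, the cause was not tested. A 2-fold threshold gives fewer calls by construction. No paired analysis was possible because animal numbers are unique to each animal.

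Genes called in females (319) were 707 with DESeq2, 517 with limma voom, 1000 without a filter and 207 with the 2-fold threshold, and 144 (without KO188) to 1479 (without Het165) with 1 library left out. In males (115) the counts were 264, 374, 375 and 61, and 41 (without KO240) to 294 (without KO255). For the average (504) they were 821, 852, 858 and 138, and 318 (without female KO188) to 931 (without female Het165). For the difference of the sexes (1) they were 243 with DESeq2, 66 with limma voom and 358 without a filter, 0 with the endothelial covariate, where Aldh3a1 had a log2 difference of 2.62 ± 0.378 (adjusted p = 0.082, range over alternatives that lost the call 0.0643 to 0.114), and 0 to 206 with 1 library left out. For Het libraries of the sexes (1501) the count was 683 with the 2-fold threshold, 35 with the covariate and 668 (without male Het204) to 1572 (without female Het165), and for KO-labelled libraries (3016) it was 1284, 753 and 2001 (without female KO166) to 2578 (without male KO247).

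With the covariate Dll4 (0.1673), Cdh19 (0.1019) and Ly6a (0.6772) changed sign between Het libraries and no longer passed. The log2 difference of Keap1 between KO-labelled females and males (0.71) was 0.7167 with the covariate, with a larger SE (0.382 against 0.223), and 0.6257 to 0.7621 with 1 library left out, none of which passed. In males the list of immediate early and dissociation stress genes did not pass with all libraries (-0.0377, adjusted p = 0.779), but it passed in opposite directions without KO247 (0.124, adjusted p = 0.0447) and without KO255 (-0.212, adjusted p = 0.00416). Proteasome subunits (-0.0845, adjusted p = 0.04) were at -0.255 without KO247 (adjusted p = 1.55e-07) and at 0.0266 without KO255 (adjusted p = 0.952), and they did not pass with an estimated correlation (adjusted p = 0.993).

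Lists called in females (8) were 2 with an estimated correlation, 4 with fry's directional test and 7 to 11 with 1 library left out. In males (5) they were 0, 0, 8 with fry's mixed test and 3 to 12. For the average (7) they were 2, 3, 13 and 6 to 11, and for the difference of the sexes (10) 0, 0, 6 and 6 to 16. For Het libraries of the sexes (18) they were 2 with an estimated correlation, 28 with fry's mixed test and 16 to 19, and for KO-labelled libraries (15) 1, 29 and 15 to 20. Genes called in both sexes were 59 with edgeR and 101 with DESeq2. Most small changes were missed, to an unequal degree. Of simulated 1.5-fold changes 10.4% were called in females, 32.8% in males, 35.8% for the average and 1.49% for the difference of the sexes.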

Other observations

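The predicted genes and their neighbours were chosen only after the results were seen, and the fixed lists and the splits before. A pair of predicted genes and the genes around them rose in KO-labelled libraries of both sexes. Gm20658 (chromosome 12, 116102769 to 116138648) went from 0.947 ± 0.189 to 71.4 ± 9.75 CPM in females (log2 6.23) and from 0.422 ± 0.389 to 56.7 ± 7.28 CPM in males (log2 7.19). It lies within the span of Vipr2, which encodes a receptor for vasoactive intestinal peptide (chromosome 12, 116077726 to 116146261), and Vipr2 rose from 2.16 to 12.9 CPM in females and from 2.37 to 11.6 CPM in males. Gm14964 (chromosome 19, 6530711 to 6532011, 27.2% of exonic bases shared with Nrxn2) rose from 0.189 to 9.84 CPM in females and from 0.298 to 6.32 CPM in males. Nrxn2, which encodes a neurexin (chromosome 19, 6418731 to 6544169), rose from 0.18 to 4.98 CPM in females and from 0.324 to 3.24 CPM in males. Counts without strand leave Gm14964 uncertain, while the exons of Gm20658 and Vipr2 share no bases.

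Of the 32 fixed lists, 8 passed in none of the 6 comparisons with camera at the preset correlation, though some passed with fry. With genotype, averaged over both sexes, the median log2 fold change and camera adjusted p were 0.112 and 0.326 for core components of the Keap1-NRF2 pair, 0.0194 and 0.883 for nuclear-encoded oxidative phosphorylation, 0.0897 and 0.679 for the integrated stress response, and -0.0208 and 0.883 for autophagy and lysosome. They were -0.0492 and 0.883 for the Notch pathway, 0.0796 and 0.728 for TGF-beta, BMP and Wnt response, 0.184 and 0.708 for sex hormone receptors and responsive genes, and -0.0982 and 0.708 for pericytes and smooth muscle. Between KO-labelled animals 4 of 13 Notch genes were lower in females, among them Notch2 (83.4 against 138 CPM), and the list did not pass (camera adjusted p = 0.0633). The sex hormone list had a median of -0.414 and a mean of 0.534 between Het libraries (camera adjusted p = 0.873).

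In the 10 splits of the 6 libraries of a comparison, 1 gave as many genes as the real split, the real split itself, for females (319, highest other split 0), males (115, highest other 2), the sexes in Het (1501, highest other 0) and the sexes in KO-labelled libraries (3016, highest other 0), and 10 splits are too few for a share under 0.05. For the average, 1 of 100 splits gave as many genes as the real 504, the real split itself, with 90 in the highest other. This argues against chance there but does not exclude it, since 100 of 200 possible splits were drawn.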
